A study of Drosophila melanogaster with 20 samples.

How the data were processed

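The deposited data are 1 table of gene counts from the heads of adult fruit flies (Drosophila melanogaster). Per the labels, flies were flash-frozen, heads were removed on dry ice, RNA was extracted with Trizol, and polyadenylated RNA was made into libraries and sequenced on an Illumina NextSeq. There were 20 libraries in 4 groups of 5: Gba1b-/- mutants and w1118 controls, each at 1 week and at 3 weeks of age. The deposited values are raw counts, which the authors made with featureCounts 2.0.0; DESeq2 is also named in the processing notes. The aligner, the genome build and the annotation release are not given in the sources used here, and neither are the strandedness of the libraries and the sex of the flies. The deposited table also gives a length for each gene in bases (unit: other), which was not used.

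The table held 24341 gene models. Of these, 17562 were fly genes, 2651 were from Acetobacter, 2854 from Lactobacillus and 1274 from Wolbachia. A symbol was given or found for 17478 of the fly genes; the 84 without one held 0.127% of all counts. In a reference annotation of the fly genome (BDGP6.54), 17479 of the fly identifiers were found, and 17409 of these (99.6%) had the same start and end as in the deposited table. Coordinates below are those of the deposited table. Bacterial genes were left out of the libraries used for testing and were compared apart. Fly genes that encode ribosomal RNA (136 gene models) stayed in the table.

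Counts were tested with edgeR 4.0.16 under R 4.3.3: filterByExpr by group with a minimum count of 10 kept 9929 genes, libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 20 libraries together (common biological coefficient of variation 0.279). The 5 contrasts were mutant against control at each age, 3 weeks against 1 week in each genotype, and the interaction, which is the mutant effect at 3 weeks minus that at 1 week. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Expression is given as CPM, from the TMM-scaled totals of fly genes. Fold changes are on the log2 scale with their standard error (SE), and logarithms used a prior count of 2.

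Before the data were examined, 38 lists of genes were fixed by symbol, and 36 of them had at least 3 measured members and were tested. They covered immunity, lysosomes and lipids, mitochondria, stress and detoxification, eye and nervous system, other tissues of the head, sex, digestion, the circadian clock, translation, proteolysis, chemical senses and cuticle. Lists were compared with all other genes by camera (limma 3.58.1) with its preset correlation of 0.01, adjusted over the 36 lists of a comparison. Camera with an estimated correlation and the rotation test fry were run beside it. For each list the members called over all 9929 genes are counted, and then those called when p-values were adjusted over the list alone.

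The rule for naming genes was also set beforehand. It takes the targeted locus and w. In the genotype comparisons it takes the 10 higher and 10 lower genes with the largest fold changes among called genes with a mean of at least 5 CPM and no overlap between the groups, and 8 of each in the age comparisons. For the interaction it takes the 10 smallest p-values at 5 CPM or more. From each list it takes up to 4 members with the smallest p. The text names part of these genes.

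Replicate libraries are numbered 1 to 5 in each group. The labels do not say whether they came from separate pools of flies, so p-values measure only the spread between these libraries. The numbers were not used to pair libraries. Alternatives chosen before the data were examined were DESeq2 1.42.0, other scalings, other filters on low counts, a fit to only the groups compared, a replicate block, a robust dispersion, a stricter threshold of 0.01 and leaving out each library in turn. After the data were seen, 4 more were added: leaving out the rRNA genes, using the rRNA share as a covariate, leaving out the 4 libraries with under 30% of counts in rRNA, and leaving out 1 control library. The method was tested on simulated counts drawn from a negative binomial distribution, with means and gene dispersions taken from these data. Fold changes were added to part of the genes. Each gene was drawn independently, so deviations that a library shares across genes were absent. Called and tested genes near the mutated locus and on each chromosome arm were compared with Fisher's exact test, two-sided. Bacterial counts were compared with exact permutation tests, two-sided. Shares of counts in single libraries carry 95% Wilson intervals (SciPy), which cover counting error only.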

Results

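Gene expression was measured by RNA sequencing in heads of Gba1b-/- mutant flies and of w1118 controls. Gba1b is 1 of the fly genes for glucocerebrosidase, the lysosomal enzyme whose human gene, GBA1, is mutated in Gaucher disease and raises the risk of Parkinson's disease. Each genotype was sampled at 1 week and at 3 weeks, with 5 libraries per group. Total counts per library ranged from 17713284 to 25086161. CPM values below are means of 5 libraries, with the standard deviation where it is given.

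The libraries differed in how much ribosomal RNA (rRNA) they held, although polyadenylated RNA was selected. The share of counts in rRNA genes was 51.4% ± 17.3 in 1-week mutants and 50.7% ± 28.9 in 1-week controls (SD, n = 5). At 3 weeks it was 57.9% ± 32.2 in mutants and 45.5% ± 4.47 in controls (SD, n = 5). The lowest share was 0.502% (95% interval 0.499 to 0.505) in replicate 2 of the 3-week mutants, and the highest was 79.2% (95% interval 79.20 to 79.23) in replicate 4 of the 1-week controls. The other 4 mutant libraries at 3 weeks held more rRNA than each of the 5 controls of that age. Counts outside rRNA ranged from 4495208 to 21592486 per library. Library totals include the rRNA counts, so scaling by totals alone, given below as an alternative, carries the rRNA share of a library into each gene. In 4 libraries the share was under 30%: replicate 3 of the 1-week mutants, replicates 1 and 5 of the 1-week controls and replicate 2 of the 3-week mutants. These 4 widened the spread within their groups, so counts of called genes without them are given beside the main counts, a choice made after the data were seen. Replicate 5 of the 1-week controls also carried transcripts of egg chambers and gut, such as Cp38 at 1169 CPM against 1.24 CPM in the other 4 libraries of its group.

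**Figure D1:**
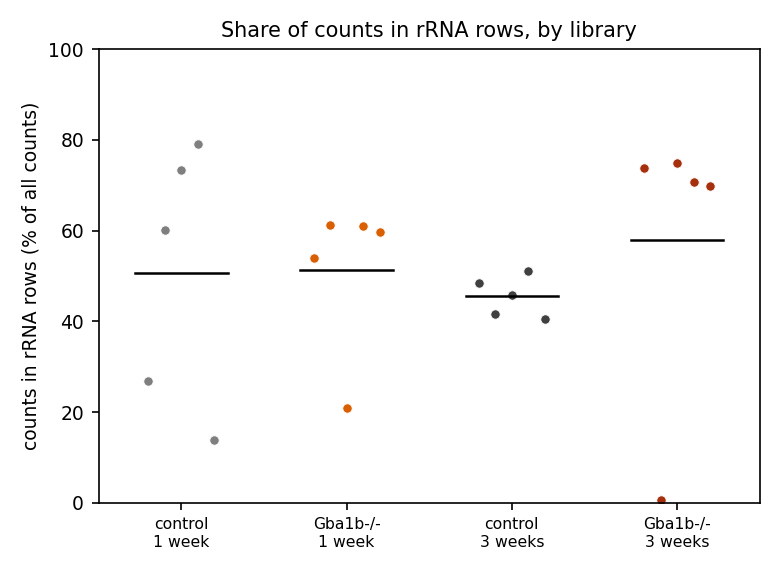
Share of all counts in rRNA genes, in percent, in each of the 20 libraries by group; dots are libraries and lines are group means. Shares ran from 0.502% to 79.2%, and 4 libraries lay under 30%.

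Gba1b itself (FBgn0051414, 3R 23704804 to 23708512) was lower in the mutants at both ages. At 1 week it fell from 11.6 ± 3.34 to 4.05 ± 0.571 CPM (SD, n = 5), a log2 change of -1.53 ± 0.19 (SE; edgeR adjusted p = 7.86e-05, and 0.265 when scaled by library totals). At 3 weeks it fell from 17 ± 1.88 to 2.74 ± 0.625 CPM (SD, n = 5), a log2 change of -2.63 ± 0.20 (SE; edgeR adjusted p = 2.03e-08). Counts remained in each mutant library, from 76 to 120 at 1 week and from 22 to 166 at 3 weeks. The gene is overlapped on the other strand by asRNA:CR44052, which had 0 to 2 counts per library. The paralogue Gba1a had 119 counts in replicate 5 of the 1-week controls and at most 10 in any other library, too few to be tested. Some neighbouring genes were more abundant in mutants. The adjacent gene Qsox4 (FBgn0051413) rose by 3.52 ± 0.62 at 1 week and 2.94 ± 0.57 at 3 weeks on the log2 scale, from a control level of 0.0740 and 0.0805 CPM. The transporter gene prt (FBgn0043005, 3R 23696372 to 23699027) rose from 4.5 ± 1.39 to 25.7 ± 6.16 CPM at 1 week (SD, n = 5). Between prt and Gba1a, CG31468, chosen after its values were seen, had 0 or 1 count per control library at 1 week and 0 in all 5 at 3 weeks. Mutant libraries held 69 to 169 and 50 to 249 of its counts. The neighbour CG10232 rose from 0.539 to 1.84 CPM at 3 weeks (edgeR adjusted p = 0.00758) and was not called at 1 week. Of the others, CG10365 fell from 27.8 to 17.6 CPM at 3 weeks (edgeR adjusted p = 0.00582), eIF3d1, CG10254, SPE and CG18754 were not called at either age, and CG10301 had no counts in mutant libraries, with too few in controls to be tested. The eye-colour gene w (FBgn0003996, X 2790599 to 2796466), which is partly deleted in w1118, had 13 counts over the 5 controls and 2158 over the 5 mutants at 1 week, and 12 against 1848 at 3 weeks. Called genes were not enriched within 1 Mb of Gba1b, where 5 of 211 were called at 1 week (odds ratio 1.15, p = 0.628, Fisher's exact test, two-sided, adjusted p = 0.769) and 32 of 211 at 3 weeks (odds ratio 0.910, p = 0.707, Fisher's exact test, two-sided, adjusted p = 0.795).

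At 1 week, the list of JAK-STAT and Turandot genes was the only list called with either correlation between heads of Gba1b-/- and control flies. Turandot genes, which encode stress-induced secreted proteins and respond to JAK-STAT signalling, were among the genes that rose most. Single genes for antimicrobial peptides, phagocytosis, autophagy and detoxification rose with them. A set of 8 genes was close to absent in the mutants. The remaining groups of genes held few or no called members.

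The 1-week comparison called 207 of 9929 genes, 132 higher and 75 lower in mutants. Of these, 126 changed by at least 1 on the log2 scale, and in 141 the 5 mutant and 5 control libraries did not overlap. Of all tested genes 2.21% had no overlap, against 0.794% by chance. Without the 4 libraries with under 30% rRNA, 1018 genes were called, 519 higher and 499 lower, and 167 of the 207 were among them. Leaving out 1 library changed the count by more than 1.5 times in 6 cases: it was 123, 120, 118 and 122 without mutant replicates 1, 2, 4 and 5, and 371 and 350 without control replicates 1 and 2. Most of the latter were lower (214 and 177). Leaving out control replicate 5, which carried egg and gut transcripts, gave 251 genes, 159 higher and 92 lower. Of the 207 main calls, 156 were among them. With no low-count filter 391 genes were called and with a minimum mean of 1 CPM 409, most of them lower (241 and 253), so the excess of higher genes depended on the filter. Fitting only the 2 groups compared gave 63 and a replicate block 133. Scaling by library totals gave 30, and of the genes named below Rel, drpr, ref(2)P, Prx6b, Cyp304a1, Cyp6w1, Ilp6, Def, tobi, Lsp1beta, Jon99Cii, Jon65Aiii and Cyp4g1 lost their call (adjusted p of 0.0565 or more).

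Of the 16 measured members of the JAK-STAT and Turandot list, 6 rose, none fell and 10 were not called (9 higher, adjusted over the list alone). Camera placed the list above other genes (adjusted p = 2.22e-13, and 0.0032 with an estimated correlation). TotA (FBgn0028396) rose from 45.8 ± 21.9 to 1252 ± 440 CPM (SD, n = 5), by 4.78 ± 0.48 on the log2 scale (SE; edgeR adjusted p = 3.76e-06). TotC rose from 9.44 to 519 CPM, TotM from 5.37 to 253 CPM and TotX from 9.17 to 75.2 CPM.

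Other immune lists were called with the preset correlation alone or not at all. Among 17 antimicrobial peptides, 3 rose, 1 fell and 13 were not called (9 higher and 2 lower, adjusted over the list alone; camera adjusted p = 1.38e-06, 0.534 with an estimated correlation). AttC rose from 28.2 ± 33.7 to 187 ± 87.2 CPM (SD, n = 5; edgeR adjusted p = 0.0128, and 0.173 when only the 2 groups compared were fitted), and Def fell by 2.17 on the log2 scale (edgeR adjusted p = 0.0149, and 0.0525 without mutant replicate 4). Of 36 genes of peptidoglycan recognition and Imd/Toll signalling, 3 rose and none fell, among them Rel, the NF-kappaB factor of the Imd pathway, by 0.47 ± 0.08, a call lost when only the 2 groups were fitted (adjusted p = 0.0741; 4 higher and 1 lower, adjusted over the list alone; camera adjusted p = 0.000177, 0.327 with an estimated correlation). None of 16 bomanins and other Toll effectors was called, none also when adjusted over the list alone, and camera placed them higher (adjusted p = 2.25e-05, 0.674 with an estimated correlation, 0.0921 without control replicate 5). Of 18 haemocyte markers 1 rose and 1 fell (camera adjusted p = 0.656). The riser was NimC4, a phagocytosis receptor also used by glia, from 0.856 to 5.27 CPM. The engulfment receptor drpr was the only called gene of 17 glial markers and rose by 0.45 ± 0.08 (camera adjusted p = 0.000263, 0.534 with an estimated correlation, 0.0606 without control replicate 5).

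Genes of stress handling rose singly. The autophagy receptor ref(2)P rose by 0.41 ± 0.07 (adjusted p = 0.173 when only the 2 groups were fitted) and was the only called gene of 27 autophagy genes (camera adjusted p = 0.219). Of 31 glutathione S-transferases, 3 rose and none fell (camera adjusted p = 0.00281, 0.674 with an estimated correlation, 0.113 without control replicate 5), with GstD5 from 0.0990 to 1.76 CPM. Of 18 antioxidant enzymes 2 rose, among them Prx6b by 0.91 ± 0.14 (camera adjusted p = 0.119). The 76 cytochrome P450s split into 3 higher and 2 lower. Their test was higher (camera adjusted p = 0.0409, 0.712 with an estimated correlation), while the median of the list was -0.01 and the mean -0.14. Cyp304a1 rose by 2.63 ± 0.50, and Cyp6w1 by 0.79 ± 0.18 (edgeR adjusted p = 0.0241, and 0.0687, 0.0779 and 0.0623 without mutant replicates 1, 2 and 4, and 0.357 when only the 2 groups were fitted). The camera adjusted p of the list was 0.0954, 0.0861 and 0.0731 without mutant replicates 1, 2 and 4, and 0.0532 and 0.495 without control replicates 4 and 5. The insulin-like gene Ilp6 rose by 0.81 ± 0.14 (adjusted p = 0.0663 when only the 2 groups were fitted), alone among 19 genes of insulin and nutrient signalling (camera adjusted p = 1).

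The 8 genes close to absent in mutants included the largest falls at both ages. CG3088 (FBgn0036015, 3L 9600490 to 9601325) fell from 517 ± 179 to 1.32 ± 0.497 CPM at 1 week (SD, n = 5), a log2 change of -8.64 ± 0.44 (SE; edgeR adjusted p = 1.77e-10). CG8343 (FBgn0040502, 2R 6179726 to 6180356) fell from 553 to 2.09 CPM, CG8329 from 182 to 0.750 CPM and CG9676 from 273 to 1.74 CPM. The others were CG7829, CG11211, CG30033 and CG32523. At 3 weeks the 8 genes stood at 0.170 to 2.25% of the control mean, and at 1 week at 0.255 to 2.35%. Several of them encode predicted secreted serine proteases.

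Among fat body markers, 1 of 15 rose and 3 fell (camera adjusted p = 0.656). The sugar-responsive glucosidase gene tobi fell by 2.02 on the log2 scale (SE 0.30), the storage protein gene Lsp1beta fell by 2.39 (SE 0.37), and Obp99b rose by 3.31 ± 0.73 (edgeR adjusted p = 0.0192, and 0.0631 without mutant replicate 1). Calls of Jon99Cii, Jon65Aiii and Cyp4g1 rested on control replicate 5. Without it their log2 changes were -0.77, -0.00067 and 0.18, and none was called. Jon99Cii and Jon65Aiii belong to the 16 gut and digestive enzymes, of which 3 fell (camera adjusted p = 0.00402, 0.712 with an estimated correlation, 0.344 without control replicate 5). The calls of Jon99Cii, Jon65Aiii and Cyp4g1 were also lost without any 1 mutant library, at edgeR adjusted p of 0.061 or more.

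Apart from the gut and digestive enzymes, lower lists at 1 week held no called member. They were the 66 nuclear-encoded OXPHOS genes (median log2 change -0.21, camera adjusted p = 1.25e-08, 0.429 with an estimated correlation), the 83 cytosolic ribosomal proteins (-0.09, 0.00317, 0.712) and the 72 mitochondrial ribosomal proteins (-0.13, 0.00448, 0.712, and 0.632 without control replicate 5). For cytosolic ribosomal proteins the camera adjusted p was 0.0902 without control replicate 3. The synapse list (31 genes) and the male-biased list (5 genes) were called higher with no called member (camera adjusted p = 0.0298 each, 0.901 and 0.534 with an estimated correlation). Without control replicate 5 the synapse list was lower (camera adjusted p = 0.0479) and the male-biased list lost its call (0.238). Without mutant replicates 1 and 5 and control replicate 1 the synapse list was at 0.0954, 0.105 and 0.0519, and the male-biased list was at 0.112 without mutant replicate 1 and at 0.0539 and 0.0594 without control replicates 1 and 3.

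**Figure D2:**
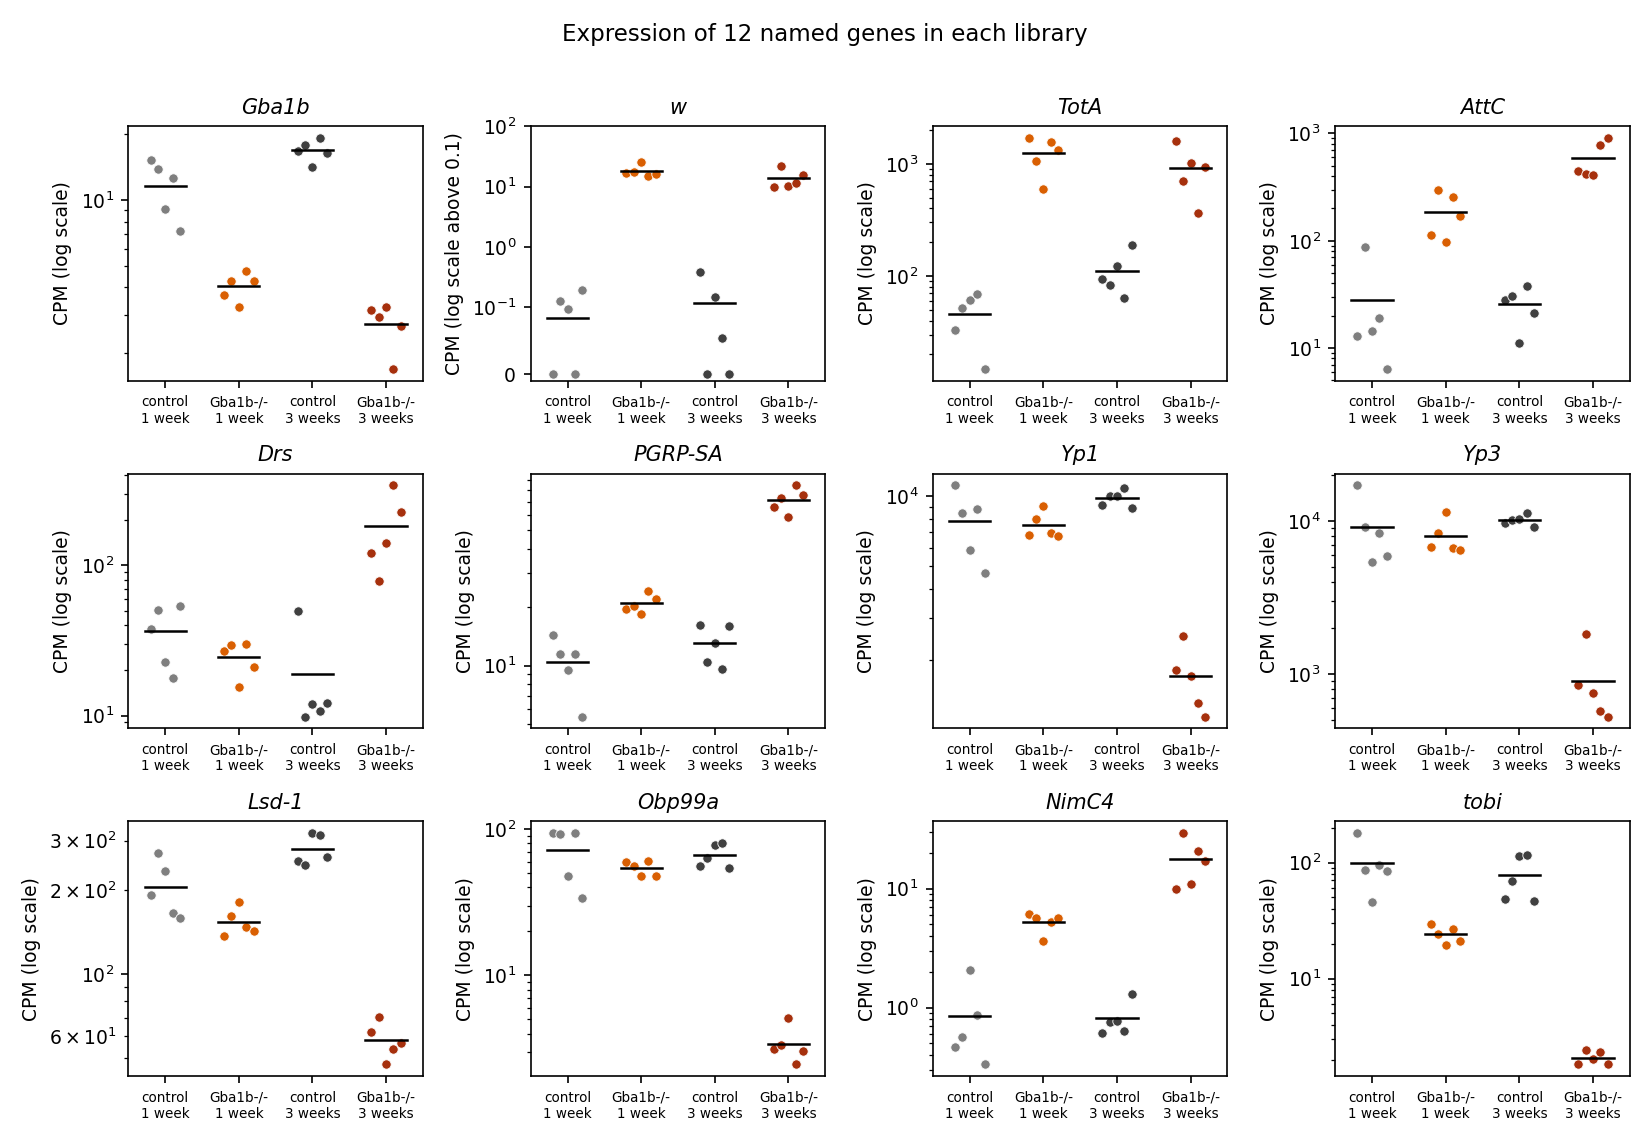
CPM on a logarithmic axis (for w linear below 0.1) of 12 named genes in the 4 groups; dots are libraries and lines are group means. TotA rose from 45.8 to 1252 CPM at 1 week, and Yp1 fell from 9749 to 1697 CPM at 3 weeks.

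At 3 weeks many more genes were called between mutant and control heads than at 1 week. Most of the libraries with under 30% rRNA were in the 1-week groups, where they widened the spread. Without these libraries the counts were 1018 at 1 week and 5490 at 3 weeks. Fewer libraries were then left at 1 week than at 3 weeks. Each mutant library left at 3 weeks also held more rRNA than each control, so share and genotype cannot be told apart there. With the rRNA share as a covariate over all 20 libraries the counts were 246 at 1 week and 2795 at 3 weeks. The interaction, which tests the difference between the ages, called 572 genes. More genes of antimicrobial peptides, Toll effectors and peptidoglycan recognition were called higher than at 1 week, though the interaction called few of them. Yolk protein genes, part of the fat body and lipid storage genes and most cytosolic ribosomal protein genes fell. The ribosomal list was the only one called with either correlation. Lists for eye pigment, phototransduction and detoxification were lower with the preset correlation alone. Genes of sphingolipid metabolism, the pathway of glucocerebrosidase, changed in both directions.

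At 3 weeks 1629 of 9929 genes were called, 743 higher and 886 lower in mutants. Of these, 520 changed by at least 1 on the log2 scale, and in 1441 the groups did not overlap (19.7% of all tested genes, 0.794% by chance). Leaving out the 4 libraries with under 30% rRNA gave 5490 genes, 2739 higher and 2751 lower, and 1628 of the 1629 were among them. At this age rRNA share and genotype went together in all but 1 library. With the rRNA share as a covariate 2795 genes were called, 1395 higher and 1400 lower, and 1624 of the 1629 were among them. Scaling by library totals gave 153. Calls lost by it include those of PGRP-SC2 (adjusted p = 0.0509), FASN1 (0.591), Cyp4d20 (0.153), v (0.302), AkhR (0.486), RpS4, Rel and ifc (1 each), while their directions stayed. Of the genes called at 1 week, 112 were higher at both ages (9.88 by chance), 35 were lower at both (6.69 by chance) and 4 were called in opposite directions. Across all 9929 genes the 2 sets of fold changes had a Pearson correlation of 0.342; genes are not independent replicates.

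Immune effectors were also higher at this age. Of 17 antimicrobial peptides, 13 rose, 1 fell and 3 were not called (the same numbers, adjusted over the list alone; camera adjusted p = 1.04e-07, 0.288 with an estimated correlation). AttC rose from 25.7 ± 10.1 to 593 ± 236 CPM (SD, n = 5), by 4.53 ± 0.62 on the log2 scale (SE; edgeR adjusted p = 2.35e-05). Dro rose from 41.7 to 518 CPM, Drs, the main Toll target, from 18.8 to 182 CPM, and CecC from 2.04 to 19.8 CPM. Among 16 bomanins and other Toll effectors 8 rose and none fell, with BomT2 up by 1.71 ± 0.32 (9 higher, adjusted over the list alone; camera adjusted p = 0.00203, 0.717 with an estimated correlation). Of 36 genes of peptidoglycan recognition and Imd/Toll signalling, 8 rose and 5 fell (camera adjusted p = 0.195, 0.717 with an estimated correlation). PGRP-SA, a receptor of the Toll pathway, rose from 13.1 ± 3.07 to 71.5 ± 10.2 CPM (SD, n = 5), PGRP-SC2 rose from 0.485 to 25.6 CPM, and Rel rose by 0.69 ± 0.08. The JAK-STAT and Turandot list had 9 higher and 1 lower of 16 (camera adjusted p = 7.37e-05, 0.0696 with an estimated correlation), with TotA at 110 against 923 CPM and TotX at 13.6 against 107 CPM.

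Single haemocyte and engulfment genes rose. NimC4 rose from 0.821 to 17.6 CPM, by 4.41 ± 0.41 on the log2 scale (edgeR adjusted p = 2.41e-07), and He by 2.36 ± 0.46. In all, 3 of 18 haemocyte markers rose and 2 fell (camera adjusted p = 0.555). The engulfment receptor drpr rose from 55.5 ± 2.99 to 114 ± 10.8 CPM (SD, n = 5), and of 17 glial markers 1 rose and 1 fell (camera adjusted p = 0.863).

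Yolk transcripts and part of the fat body markers fell. Yp1 fell from 9749 ± 769 to 1697 ± 535 CPM (SD, n = 5), a log2 change of -2.52 ± 0.23 (SE; edgeR adjusted p = 2.51e-07). Yp2 changed by -2.93 ± 0.28 and Yp3 by -3.48 ± 0.36. These are 3 of the 4 female-biased markers (camera adjusted p = 6.74e-05, 0.0696 with an estimated correlation). Of 5 male-biased markers 1 rose and 1 fell (camera adjusted p = 0.995); the faller, Obp99a, went from 66.3 to 3.42 CPM. Of 15 fat body markers 2 rose and 6 fell (2 higher and 8 lower, adjusted over the list alone; camera adjusted p = 6.74e-05, 0.0611 with an estimated correlation). The gene tobi fell from 78.5 to 2.08 CPM, a log2 change of -5.22 ± 0.36.

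Of 23 genes of lipid storage and fatty acid metabolism, 2 rose, 10 fell and 11 were not called (3 higher and 13 lower, adjusted over the list alone; camera adjusted p = 3.12e-06, 0.0611 with an estimated correlation). The lipid droplet genes Lsd-1 and Lsd-2 fell, with log2 changes of -2.26 ± 0.15 and -0.85 ± 0.07, and the fatty acid synthase FASN1 fell from 1598 to 831 CPM (-0.94 ± 0.11). The adipokinetic hormone receptor AkhR fell by 1.10 (SE 0.11), while the insulin antagonist ImpL2 rose by 0.95 ± 0.11. In the insulin and nutrient signalling list 3 of 19 rose and 3 fell (camera adjusted p = 0.882).

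Ribosomal protein genes fell together by small amounts. Of 83 cytosolic ribosomal proteins, 59 fell, none rose and 24 were not called (67 lower, adjusted over the list alone). Their median log2 change was -0.45, and camera called the list with either correlation (adjusted p = 7.72e-28, and 0.0184 with an estimated correlation). RpS4 fell by 0.76 (SE 0.08) and RpL10Ab fell by 0.57 (SE 0.07). None of 72 mitochondrial ribosomal proteins was called (camera adjusted p = 0.603). Of 66 nuclear-encoded OXPHOS genes 10 fell and none rose (median -0.19, camera adjusted p = 0.000121, 0.506 with an estimated correlation). The 13 mitochondrially encoded mRNAs held no called gene (camera adjusted p = 0.737).

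In the pathway of glucocerebrosidase, 7 of 17 sphingolipid genes rose and 2 fell (7 higher and 3 lower, adjusted over the list alone; camera adjusted p = 0.181). The dihydroceramide desaturase ifc rose from 24.6 ± 1.9 to 50.8 ± 5.1 CPM (SD, n = 5), by 1.05 ± 0.14 on the log2 scale, and the sphingomyelinase-like CG3376 rose by 0.79 ± 0.11. Of 28 lysosomal genes 3 rose and 6 fell (camera adjusted p = 0.457). Sap-r, whose saposins assist glucocerebrosidase, rose by 0.40 ± 0.07, and the lysosomal transporter spin fell by 0.64 (SE 0.11). Of 19 V-ATPase subunits 1 rose (camera adjusted p = 0.882). Of 27 autophagy genes 2 rose (camera adjusted p = 0.965), with ref(2)P up by 0.43 ± 0.07.

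Lists of vision and detoxification genes were lower with the preset correlation alone. Of 13 eye pigment genes other than w, 7 fell and none rose (camera adjusted p = 7.37e-05, 0.0696 with an estimated correlation), with v at -1.35 ± 0.15. Of 33 phototransduction genes 9 fell and none rose (camera adjusted p = 7.3e-05, 0.717 with an estimated correlation). The carotenoid receptor ninaD fell by 1.60 (SE 0.24) and the opsin Rh4 fell by 0.88 (SE 0.16). The eye-colour gene w also differed between the genotypes, with 12 counts over the controls and 1848 over the mutants at 3 weeks. An effect of w on eye pigment and phototransduction genes cannot be told apart from an effect of Gba1b. Of 76 cytochrome P450s 6 rose and 21 fell (camera adjusted p = 0.00112, 0.371 with an estimated correlation), with Cyp4d20 at -1.61 ± 0.15. Of 22 UDP-glycosyltransferases 1 rose and 8 fell (camera adjusted p = 0.000216, 0.21 with an estimated correlation), with Ugt37A3 at -3.84 ± 0.37. Odorant-binding proteins, 24 in number, had 1 higher and 7 lower (camera adjusted p = 0.0045, 0.717 with an estimated correlation). The 34 proteasome subunits were called higher with 1 called member (camera adjusted p = 0.0186, 0.941 with an estimated correlation, 0.148 without mutant replicate 2).

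Lists without a call at 3 weeks still held single changed genes. Among 31 glutathione S-transferases 3 rose, GstD5 by 2.62 ± 0.47, and 5 fell. The small heat shock gene Hsp23 rose by 1.41 ± 0.13, 1 of 19 heat shock proteins that rose, while 3 fell. The neuropeptide gene Nplp3 fell by 1.90 (SE 0.26), 1 of 3 that fell of 27, and 2 rose. Antioxidant enzymes had 2 higher and 5 lower of 18, ER unfolded protein response genes 3 lower of 22, synapse genes 1 higher and 1 lower of 31, muscle markers 2 higher of 20, and gut and digestive enzymes 1 higher and 2 lower of 16. Chemosensory receptors had 2 higher and 3 lower of 34, and cuticle proteins 3 higher and 7 lower of 28.

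**Figure D3:**
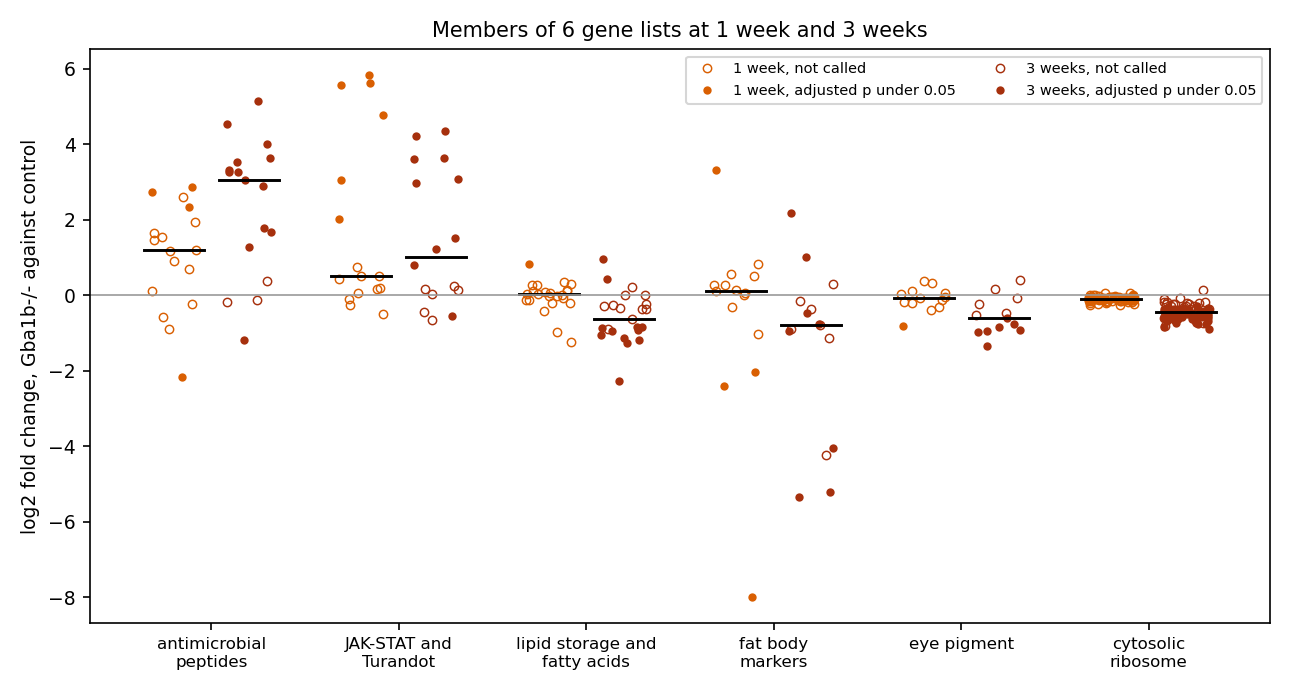
Log2 fold change, mutant against control, of the measured members of 6 gene lists at 1 week and at 3 weeks; each dot is a gene, filled when its edgeR adjusted p was under 0.05, and black bars are medians. The median of the antimicrobial peptides was 1.2 at 1 week and 3.06 at 3 weeks, and that of the cytosolic ribosomal proteins was -0.09 and -0.45.

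The interaction asks which of these mutant effects differed between the ages. Most of the genes it called had a lower mutant effect at 3 weeks than at 1 week. Lists of lipid storage, fat body, female-biased and cytosolic ribosomal protein genes were lower with either correlation. Immune genes were among the fewer genes with a higher effect at 3 weeks.

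The test called 572 of 9929 genes, 171 with a higher and 401 with a lower mutant effect at 3 weeks. Without the 4 libraries with under 30% rRNA it called 4026 genes, 1957 higher and 2069 lower, and 554 of the 572 were among them. With the rRNA share as a covariate it called 1087. Scaling by library totals left 4 genes, Obp99a the only one of those named here, with CG8654 at an adjusted p of 0.116, Drs at 0.148, Yp1 at 0.439 and Lsd-1 at 0.558. The smallest p was that of CG8654, whose mutant level went from 46.6 to 9.05 CPM with age while controls went from 54.8 to 104 CPM, a difference of -3.28 ± 0.22 (SE; edgeR adjusted p = 3.79e-08). CG42329 (-2.16 ± 0.18), CG15096 (-2.41 ± 0.22), Mtap (-1.10 ± 0.10), fbp (-1.91 ± 0.19) and ScsbetaA (-0.99 ± 0.10) were also lower.

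The lipid list had 8 of 23 genes lower and none higher (camera adjusted p = 2.28e-09, 0.0135 with an estimated correlation), with Lsd-1 at -1.85 ± 0.20, Lsd-2 at -0.96 ± 0.10 and FASN1 at -1.22 ± 0.16. Fat body markers had 5 of 15 lower and none higher (camera adjusted p = 9.84e-08, 0.0135 with an estimated correlation), with tobi at -3.19 ± 0.44. The female-biased markers had 3 of 4 lower (camera adjusted p = 5.41e-08, 0.0162 with an estimated correlation), with Yp1 at -2.47 ± 0.32, Yp2 at -2.96 ± 0.38 and Yp3 at -3.27 ± 0.47. The cytosolic ribosomal proteins had 19 of 83 lower (36 lower, adjusted over the list alone; camera adjusted p = 9.19e-23, 0.0148 with an estimated correlation), with RpS4 at -0.70 ± 0.11. Obp99a (-3.87 ± 0.35), AkhR (-1.21 ± 0.15) and v (-1.46 ± 0.21) were also lower. The fall of Gba1b itself was larger at 3 weeks (-1.10 ± 0.27, edgeR adjusted p = 0.0194).

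Among higher effects at 3 weeks, Drs differed by 3.86 ± 0.67, PGRP-SA by 1.45 ± 0.28, drpr by 0.58 ± 0.11, Hsp23 by 1.4 ± 0.18 and ImpL2 by 1.16 ± 0.15. Drs was the only called one of 17 antimicrobial peptides (2 higher, adjusted over the list alone; camera adjusted p = 0.00352, 0.712 with an estimated correlation, 0.0501 without control replicate 2 of 1 week). Other lists called lower were cytochrome P450s, UDP-glycosyltransferases, phototransduction, eye pigment, antioxidant enzymes, glutathione S-transferases and odorant-binding proteins, at estimated-correlation adjusted p of 0.102 to 0.615 for the first 4 and 0.16 to 0.712 for the rest. The glutathione S-transferases lost their call without 1-week control replicates 1 and 5 (0.0626 and 0.075) and without 3-week mutant replicate 2 (0.173), and the odorant-binding proteins without 1-week control replicate 5 (0.0605).

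In control heads, part of the cytochrome P450, UDP-glycosyltransferase, immune signalling and lipid genes rose from 1 to 3 weeks. Part of the nuclear-encoded OXPHOS and muscle genes fell. Among clock genes, tim, per and vri fell and Clk rose, and the labels do not give the time of day of collection. The 1-week controls include the library with egg and gut transcripts, so apparent falls of such genes rested on it.

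The comparison called 620 of 9929 genes, 364 higher and 256 lower at 3 weeks. In 459 the groups did not overlap (6.93% of all tested genes, 0.794% by chance). Without the 4 libraries with under 30% rRNA, 3798 genes were called, 2013 higher and 1785 lower, and 550 of the 620 were among them. The count was 941 without 1-week replicate 1, and 403, 373, 381, 361 and 385 without 3-week replicates 1 to 5. Leaving out 1-week replicate 5 gave 770 genes, and 466 of the 620 were among them. Fitting only the 2 groups compared gave 141 and a replicate block 368. Without 1-week replicate 1, with no low-count filter and with a minimum mean of 1 CPM, most called genes were lower (477 of 941, 432 of 789 and 454 of 843). Scaling by library totals gave 28. Calls lost by it include those of CG42329 (adjusted p = 0.0721), Hsp70Aa (0.13), per (0.226), Clk (0.347), Ugt302C1 (0.749), Cyp6a13 (0.854), Rel and Mlc1 (1 each). Jon65Aiii, Jon99Ciii and Cp38 fell, with log2 changes of -11.21, -10.50 and -11.22. Without 1-week replicate 5 these were -3.01, -3.18 and -3.55, and none was called. Scp1 fell by 4.97 (SE 1.00) with the same library in the group, a call lost when only the 2 groups were fitted (adjusted p = 0.0838).

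Of 76 cytochrome P450s 23 rose and 1 fell (34 higher and 2 lower, adjusted over the list alone; camera adjusted p = 1.36e-17, 0.0139 with an estimated correlation), Cyp6a13 by 0.80 ± 0.09. Of 22 UDP-glycosyltransferases 9 rose and none fell (camera adjusted p = 7.04e-11, 0.0181 with an estimated correlation), Ugt302C1 by 0.84 ± 0.09. Of 36 genes of peptidoglycan recognition and Imd/Toll signalling 6 rose (camera adjusted p = 1.53e-07, 0.0281 with an estimated correlation), Rel from 63.6 to 95 CPM. Of 16 JAK-STAT genes 3 rose, among them vir-1 by 0.52 ± 0.12 with adjusted p = 0.14 when only the 2 groups were fitted (camera adjusted p = 0.000776, 0.143 with an estimated correlation). The antimicrobial peptides held no called gene (camera adjusted p = 0.727). Of 23 lipid genes 5 rose (camera adjusted p = 2.92e-06, 0.0378 with an estimated correlation), with the lipase bmm up by 0.62 ± 0.09 and Lsd-2 by 0.40 ± 0.07 (adjusted p = 0.0566 for Lsd-2 when only the 2 groups were fitted).

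Of 66 OXPHOS genes 14 fell and none rose (28 lower, adjusted over the list alone; camera adjusted p = 4.99e-15, 0.0463 with an estimated correlation), with ND-B12 at -0.37 ± 0.07 (adjusted p = 0.0503 when only the 2 groups were fitted). Of 20 muscle markers 9 fell and none rose (17 lower, adjusted over the list alone; camera adjusted p = 3.08e-10, 0.0181 with an estimated correlation), with Mlc1 at -0.75 ± 0.10 and Mlc2 at -0.63 ± 0.08. Among 15 clock genes 1 rose and 4 fell (camera adjusted p = 0.0357, 0.183 with an estimated correlation, and 0.0794 and 0.0709 without 1-week replicates 1 and 4). The gene tim fell from 133 ± 26.1 to 23.1 ± 1.80 CPM (SD, n = 5), per from 37.5 to 6.27 CPM and vri from 56.2 to 23.5 CPM, while Clk rose from 18.1 to 35.2 CPM. Hsp70Aa and Hsp70Ab, near-identical copies whose reads cannot be told apart with certainty, rose by 2.17 ± 0.19 each. Of 19 heat shock proteins 6 rose and 3 fell; the list was called higher (camera adjusted p = 0.0452, 0.549 with an estimated correlation), with a median of -0.21 and a mean of -0.00. It lost this call without 1-week replicates 2, 3 and 4 (0.117, 0.15 and 0.119). CG42329 rose by 2.11 ± 0.13, Srg3 by 1.60 ± 0.18 and the olfactory receptor gene Ir75a by 1.39 ± 0.15.

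Further lists called with age in controls did not hold with an estimated correlation, at adjusted p of 0.146 to 0.704. Higher were lysosomal genes (4 rose, 1 fell), haemocyte markers (4 rose), glutathione S-transferases (4 rose) and cytosolic ribosomal proteins (none called). Mitochondrial ribosomal proteins were lower (3 fell). The remaining higher lists lost their call without 1-week replicate 5: eye pigment (0.0759), glial markers (0.0695), fat body markers (0.111), odorant-binding proteins (0.14), chemosensory receptors (0.629) and bomanins (0.671, then lower). So did the lower gut and digestive enzymes (0.514) and proteasome (0.279, then higher). Autophagy, called higher, was not called without 1-week replicates 2, 3 and 4 (0.117, 0.0923 and 0.141) or without 3-week replicates 1, 3 and 5 (0.0529, 0.0554 and 0.0693). Bomanins were also at 0.0625 without 1-week replicate 1 and at 0.0906 and 0.0571 without 3-week replicates 1 and 2, and the proteasome at 0.0555 without 3-week replicate 2.

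In mutant heads, part of the immune genes and single engulfment genes rose with age, and yolk genes and part of the fat body, lipid and ribosomal protein genes fell. None of the 15 lists called with the preset correlation was called with an estimated one (adjusted p of 0.0626 to 0.776). The OXPHOS and muscle lists were lower in both genotypes with the preset correlation, and the interaction called neither (camera adjusted p = 0.679 and 0.0779). Each of the groups compared held 1 library of low rRNA.

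The comparison called 1350 of 9929 genes, 668 higher and 682 lower at 3 weeks. In 1031 the groups did not overlap (13.9% of all tested genes, 0.794% by chance). Without the 4 libraries with under 30% rRNA, 4001 genes were called, 2039 higher and 1962 lower, and 1343 of the 1350 were among them. With the rRNA share as a covariate 2524 were called. Scaling by library totals gave 37. Calls lost by it include those of Drs (adjusted p = 0.0571), Yp3 (0.127), PGRP-SA (0.14), NimC4 (0.159), tim (0.175), Yp1 (0.21), drpr and RpS4 (1 each). With controls, 137 genes were higher with age in both genotypes (24.5 by chance), 89 were lower in both (17.6 by chance) and 53 were called in opposite directions. Across genes the Pearson correlation of the fold changes was 0.186.

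Of 17 antimicrobial peptides 5 rose and none fell (camera adjusted p = 0.000332, 0.549 with an estimated correlation), with Drs up by 2.89 ± 0.49. Of 36 recognition and signalling genes 9 rose and 2 fell (camera adjusted p = 0.00107, 0.223 with an estimated correlation), PGRP-SA by 1.78 ± 0.20. Bomanins had 5 of 16 higher (camera adjusted p = 0.0342, 0.776 with an estimated correlation), and lost the call without 1-week replicates 2 and 3 (0.0891 and 0.0873) and 3-week replicates 4 and 5 (0.0865 and 0.0593). Haemocyte markers had 5 of 18 higher (camera adjusted p = 0.00383, 0.411 with an estimated correlation, 0.0917 without 3-week replicate 2), with NimC4 up by 1.75 ± 0.35. The glial gene drpr rose by 0.79 ± 0.08.

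Yolk genes fell, Yp1 at -2.14 ± 0.23, Yp2 at -2.51 ± 0.28 and Yp3 at -3.13 ± 0.36, and the female-biased list was lower (camera adjusted p = 9.26e-07, 0.0626 with an estimated correlation). Of 15 fat body markers 2 rose and 5 fell (camera adjusted p = 0.000523, 0.136 with an estimated correlation), with tobi at -3.52 ± 0.34 and Lsp1beta at -3.11 ± 0.44. Of 23 lipid genes 3 rose and 9 fell (camera adjusted p = 0.000523, 0.168 with an estimated correlation), with Lsd-1 at -1.4 ± 0.15 and FASN1 at -0.84 ± 0.11. Of 83 cytosolic ribosomal proteins 29 fell and none rose (53 lower, adjusted over the list alone; camera adjusted p = 1.81e-17, 0.0626 with an estimated correlation), with RpS4 at -0.59 ± 0.08. Of 66 OXPHOS genes 24 fell and none rose (camera adjusted p = 1.1e-10, 0.168 with an estimated correlation), with ATPsynC at -0.50 ± 0.07. Muscle markers had 6 of 20 lower, with Mlc2 at -0.55 ± 0.08, and mitochondrial ribosomal proteins 3 of 72 lower (camera adjusted p = 0.00249 and 0.000757, 0.316 and 0.549 with an estimated correlation).

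Obp99a (-3.99 ± 0.28), Ugt37A3 (-3.21 ± 0.37), CG42586 (-4.06 ± 0.30), Nplp3 (-1.99 ± 0.26) and AkhR (-0.67 ± 0.11) were also lower. Phototransduction had 9 of 33 lower, with retinin at -1.32 ± 0.19, and eye pigment 4 of 13 lower (camera adjusted p = 8.04e-05 and 0.0265, 0.573 and 0.411 with an estimated correlation). The clock genes tim (-1.64 ± 0.12), per (-2.08 ± 0.39) and vri (-0.94 ± 0.17) fell. Ir75a rose by 1.4 ± 0.15, ifc by 1.09 ± 0.14 and Sap-r by 0.51 ± 0.07. Antioxidant enzymes and cuticle proteins were called lower (camera adjusted p = 0.0353 and 0.0265, 0.316 and 0.573 with an estimated correlation). Antioxidant enzymes lost the call without 1-week replicates 1 and 2 (0.0543 and 0.0801) and 3-week replicate 2 (0.0936), and cuticle proteins without 1-week replicate 2 (0.0654) and 3-week replicates 1 and 2 (0.0554 and 0.0682).

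No list called in these 5 comparisons changed direction under DESeq2 size factors, upper-quartile scaling or scaling by library totals alone. By library totals the median log2 change of all genes at 3 weeks moved from 0.03 to -0.09, that of the age effect in controls from -0.10 to 0.02 and that of the interaction from 0.11 to -0.01. Across chromosome arms, called genes were fewer than elsewhere on X at 3 weeks (13.2% against 17%, odds ratio 0.740, p = 0.000104, Fisher's exact test, two-sided, adjusted p = 0.000754) and on arm 4 (3 of 92). Counts of Acetobacter, Lactobacillus and Wolbachia genes did not separate the genotypes at either age. In 12 exact permutation tests, two-sided, the lowest p was 0.302, for Wolbachia at 3 weeks (709 ± 411 in mutants and 501 ± 61.9 in controls, in CPM of fly counts outside rRNA; SD, n = 5; adjusted p = 1).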

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

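The 8 tests of causes below were chosen after the results were seen; the 5 comparisons with other splits of the libraries were planned.

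Of 286 groups of 5 values (a named gene or a library measure in 1 group), 34 held a value whose gap to the nearest other library exceeded 0.71 of the group's range; chance gives this in about 5% of groups. Replicate 5 of the 1-week controls accounted for 10 of them. It was highest for Cp38 (gap 0.864), Jon65Aiii (0.894), Jon99Cii (0.876), Jon99Ciii (0.827), Cyp4g1 (0.88) and Hsp23 (0.721), and lowest for Cyp6w1 (0.791), CG3088 (0.792), CG8343 (0.732) and CG8654 (0.73). Replicate 2 of the 3-week mutants accounted for 7: the lowest rRNA share (0.502%, gap 0.93), the most genes with 10 counts (10341, gap 0.751), the highest CG3376 (0.742), spin (0.775) and per (0.869), and the lowest CG9676 (0.731) and Ir75a (0.867). Replicate 3 of the 1-week mutants accounted for 6: the lowest rRNA share (20.9%, gap 0.818), NimC4 (0.714) and Cyp4g1 (0.787), and the highest w (0.722), prt (0.77) and per (0.788).

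Replicate 1 of the 3-week controls held the highest Drs (49.4 CPM, gap 0.866), Jon65Aiii and Cp38 (gap 1 each, the other 4 libraries at 0) and the lowest CG9676 (0.734) and CG11211 (0.781). Replicate 1 of the 1-week controls was highest for Hsp70Aa (0.781) and Hsp70Ab (0.756). Single values lay apart in replicate 3 of the 1-week controls (Cyp304a1 highest, 0.784), replicate 4 of the 3-week controls (drpr lowest, 0.722), replicate 5 of the 3-week controls (Sap-r highest, 0.723) and replicate 4 of the 3-week mutants (TotX lowest, 0.738).

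Among the genes named in the comparisons of mutants with controls, the mutant effect differed between the ages in 27, by the edgeR interaction. Genes named for the interaction alone, such as CG8654, are given above and are not among them. Values are the log2 effect at 3 weeks minus that at 1 week. Lower at 3 weeks were Gba1b (-1.10), tobi (-3.19), Lsp1beta (-2.96), Yp1 (-2.47), Yp2 (-2.96), Yp3 (-3.27), Obp99a (-3.87), FASN1 (-1.22), Lsd-1 (-1.85), Lsd-2 (-0.96), RpS4 (-0.70), RpL10Ab (-0.505), spin (-0.741), Ugt37A3 (-3.27), Cyp4d20 (-1.52), v (-1.46), ninaD (-1.36), Nplp3 (-1.74) and AkhR (-1.21). Higher at 3 weeks were drpr (0.579), Drs (3.86), PGRP-SC2 (5.52), PGRP-SA (1.45), ifc (0.987), CG3376 (0.535), Hsp23 (1.4) and ImpL2 (1.16).

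In replicate 5 of the 1-week controls, all 7 measured ovary genes and 13 of 16 gut genes were at their highest of the 20 libraries. A low rRNA share does not by itself bring such transcripts, since the highest median excess of the ovary genes among the other 3 libraries with low rRNA was -0.02 (-0.02497) on the log2 scale. The excess in replicate 5 is consistent with RNA of abdominal organs in that library: its median was 7.55 for the ovary genes, 5.77 for the gut genes, -0.73 for phototransduction and -1.27 for synapse genes. The heads were cut from frozen bodies, and how such RNA came into the library was not tested. No biological explanation within the design applies to a single library.

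The 8 genes close to absent in the mutants at both ages stood at 0.170 to 2.35% of the control mean. Digestive tissue in the control libraries is argued against, as the gut list had a median log2 change of only -0.51 at 3 weeks. Linkage to the mutated locus is argued against, since 0 of the 8 genes lie within 2 Mb of Gba1b; the 1 on the same arm, CG7829, is 6.11 Mb away. The genes lie on 4 chromosome arms, and another difference between the mutant and control stocks cannot be told apart from an effect of Gba1b, because the design holds no backcrossed or rescued line. Both may contribute.

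The fall of yolk protein and fat body genes at 3 weeks was weighed against 3 causes. The rRNA share is argued against as the whole cause by the fit with it as a covariate, where the median log2 change of Yp1 to Yp3 was -3.10. At 3 weeks only mutant replicate 2, of low rRNA, separates share from genotype. Its Yp1 was at 2520 CPM, against 8846 to 10780 CPM in controls. Leaving out the 4 libraries of low rRNA cannot test this cause, since each mutant library left at 3 weeks held more rRNA than each control. Less fat body RNA is argued against as the whole cause by apolpp, Apoltp and fon, also made in the fat body, with a median log2 change of -0.37. They were at -0.88 ± 0.31, -0.37 ± 0.17 and -0.15 ± 0.23 (SE), and were chosen after the results were seen. Of other fat body markers, Lsp2 was at -4.05 ± 0.65 (SE), while the gene to rose. Without the 4 libraries of low rRNA, apolpp (-0.74), Apoltp (-0.30) and fon (-0.36) were called lower, so a smaller loss of fat body RNA stays open. Males among the mutant flies are argued against as the whole cause by fit, a female-biased gene, at 0.30 ± 0.33 (SE), and by Obp99a, a male-biased gene, at -4.28. Other male-biased genes went the other way, to at 1.01 ± 0.25 and lncRNA:roX1 at 0.83 ± 0.41 (SE; 1.2 and 0.98 without the 4 libraries), so a smaller share of males stays open. A specific lowering of these transcripts in mutants between 1 and 3 weeks may explain the pattern and remains a hypothesis, as it was found and tested on the same libraries.

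Chance in how libraries fell into groups was tested with 100 splits of the libraries per comparison, the real one included. This test cannot exclude it at 1 week, where 2 of 100 splits called as many genes as the real 207. The highest other split called 1170 genes, several times the real count, which points to a structure of the samples. Splits other than the real one mix the groups compared within a side. This can widen the spread there, so few calls in them are partly built in. That split put the 3 libraries of low rRNA on the same side. Most other splits with the 3 on the same side called 0, and the rest called 35, 23 and 4. Splits without this placement called at most 25. Since few calls are partly built in, these splits cannot show how far the rRNA share accounts for the 1170 calls. Of the 3 libraries of low rRNA, mutant replicate 3 and control replicate 1 deviated alike from their group means (correlation over genes 0.743). Control replicate 5 correlated with them at 0.385 and -0.071. At 3 weeks 1 of 100 splits reached the real count, the real split itself (1629 genes, highest other 2). The same held for age in controls (620, highest other 21), age in mutants (1350, highest other 883) and the interaction (572, highest other 223). The split with 883 calls put the low-rRNA libraries of both ages, whose deviations correlated at 0.821, on the same side. Most other splits of age in mutants with that placement called 0.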

How the results depend on the processing

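Alternatives chosen beforehand are given first; the 4 that concern rRNA and replicate 5 of the 1-week controls were chosen after seeing the data.

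Counts of called genes are given in the order mutants at 1 week, mutants at 3 weeks, age in controls, age in mutants, interaction, against main values of 207, 1629, 620, 1350 and 572. DESeq2, its size factors, upper-quartile scaling and a robust dispersion left all 5 counts within 1.5 times. Scaling by library totals gave 30, 153, 28, 37 and 4. These totals include the rRNA counts, so this scaling carries the differing rRNA shares into each gene. No low-count filter gave 391 and a minimum mean of 1 CPM gave 409 at 1 week, most of them lower (241 and 253), and the cause was not tested. Fitting only the groups compared gave 63 at 1 week and 141 for age in controls. It raised the count to 2319 at 3 weeks and to 1616 for age in mutants. The counts moved both ways, so the smaller number of samples does not by itself account for them. The main fit shares 1 estimate of the spread over all groups, but replicates did not agree equally well. The lowest correlation between replicates was 0.833 in 1-week controls, 0.914 in 3-week mutants, 0.956 in 1-week mutants and 0.9895 in 3-week controls. Main adjusted p at 1 week and for age in controls can therefore be too small. A replicate block gave 133 at 1 week and 368 for age in controls. A threshold of 0.01 gave 91, 1045, 225, 792 and 274 by construction. Without any 1 library of the comparison the counts ranged from 118 to 371, 1343 to 2087, 361 to 941, 1070 to 1786 and 407 to 836.

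The rRNA share as a covariate gave 2795 at 3 weeks, 2524 for age in mutants and 1087 for the interaction. Without the 4 libraries with under 30% rRNA the counts were 1018, 5490, 3798, 4001 and 4026; these libraries widened the spread in their groups. Leaving replicate 5 of the 1-week controls out of the shared fit gave 2189 for age in mutants, a comparison it is not part of.

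Gba1b fell at both ages under each alternative. At 1 week its log2 change by library totals was -1.54 with adjusted p = 0.265, the only call it lost, and it ranged from -1.67 to -1.41 without any 1 library. At 3 weeks that range was -2.69 to -2.50. Near Gba1b no window of 0.5, 1 or 2 Mb showed enrichment. At 0.5 Mb the odds ratios were 2.26 and 1.41 (p = 0.0809 and 0.155, Fisher's exact test, two-sided). A shorter stretch, such as that of the changed neighbours prt, CG31468 and Qsox4, was not tested.

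The named genes gave 3794 values under alternatives: 3639 kept direction and call, 152 lost the call (94 of them by library totals) and 3 reversed. Cyp4g1 at 1 week ranged from -8.31 to 0.18 without any 1 library, the last without replicate 5 of the controls, and was at 0.34 without the 4 libraries, and Jon65Aiii was at 0.23 without the 4.

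The lists gave 4536 values: 4203 kept direction and call, 208 lost a call, 104 gained one and 21 reversed. All 21 were without replicate 5 of the 1-week controls, which lifted gut and ovary transcripts, or without the 4 libraries that include it. Values are camera adjusted p, with their range without any 1 library. Without replicate 5, lists lower at 1 week were phototransduction (0.00101, range to 0.783), synapse (0.0479, 0.000374 to 0.105), neuropeptides (0.0487, 0.00581 to 0.168), odorant-binding proteins (0.0169, to 0.907) and cuticle proteins (0.0198, to 0.986). With age in controls bomanins (0.671, from 0.00245) and phototransduction (0.00328, to 0.295) were lower and the proteasome (0.279, from 0.000411) higher, and the synapse list was higher in the interaction (0.0331, to 0.858). Without the 4, at 1 week mitochondrially encoded mRNAs (0.00558), phototransduction (0.000822), synapse (0.000111), neuropeptides (0.0356), odorant-binding proteins (0.0187) and cuticle proteins (0.0177) were lower. With age in controls bomanins (0.159), mitochondrially encoded mRNAs (0.0479) and chemosensory receptors (0.569) were lower and gut enzymes (0.959) and the proteasome (0.0258) higher. The interaction of the synapse list was higher (8.59e-05).

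Replicate numbers do not pair libraries. Correlations between same-numbered libraries of the groups compared ranged from -0.649 to 0.351, and the same-numbered library was the closest in 0, 2, 2 and 1 of 5 cases. In counts simulated from the means and dispersions of these libraries, the 4 direct comparisons recovered 70 to 79% of genes changed by 1 (log2). Of genes changed by 2 they recovered 95 to 99%, and the interaction recovered 40% and 86%. Deviations shared across genes within a library were not simulated, so these shares hold for the fitted model alone.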

Other observations

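The 12 comparisons of bacterial counts below were made after the table was seen to hold bacterial genes. Acetobacter genes had 1344 ± 1024 CPM of fly counts outside rRNA in 1-week controls and 1562 ± 1040 in mutants, and 2468 ± 1343 and 2637 ± 1672 at 3 weeks (SD, n = 5). Lactobacillus genes had 19 ± 13.7 and 24.9 ± 20.2 at 1 week and 18.6 ± 13.3 and 28.3 ± 17.1 at 3 weeks (SD, n = 5). Wolbachia genes had 420 ± 306 and 345 ± 151 at 1 week (SD, n = 5). The adjusted p was 1 in each exact permutation test, two-sided. Polyadenylated RNA was selected, so bacterial transcripts were measured as a residue.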
